A study of Cannabis sativa with 12 samples.

How the data were processed

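mRNA libraries were made from leaves of Cannabis sativa of the variety Pink pepper, with 12 libraries in 4 groups of 3 (control, drought, Trichoderma hamatum, and drought with T. hamatum), per the labels' protocols. Seedlings grew for 14 days in trays and 30 days in pots. Irrigation was stopped for 10 days before sampling in the drought groups, and conidia of T. hamatum, a soil fungus used as a plant symbiont, were given to the soil around the roots at 50000000 per kg soil 13 days before sampling. RNA was extracted with an RNeasy Micro kit and libraries were made with a TruSeq mRNA kit, per the labels' protocols.

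The authors deposited raw counts of reads per annotated gene, 1 table for each library, and 1 table of the whole series with normalized signal. The submitters' processing notes name cutadapt 4.4 and DESeq2, the latter with no version. The genome build, annotation, aligner settings, counting options and strand setting are not given in the sources used here. In the deposited normalized table each value was the raw count divided by 1 factor for its library, and these factors equalled the median-of-ratios size factors recomputed from the counts (ratio 1 in all 12 libraries), so that table holds the same measurements as the counts and was not tested separately. No row of the count tables was without a gene name.

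Each library had counts for 34253 genes. Of these, 33774 matched a gene in a RefSeq table of the assembly ASM2916894v1, and the 479 others were numbered tRNA names. The table holds 35194 genes, of which the 941 not counted here were all pseudogenes. Because the authors' build is not given, the table was used only for names, gene classes and the order of neighbouring genes. It holds 0 gene descriptions, and most of its symbols are locus numbers. For that reason the 44 gene lists fixed beforehand as patterns on gene descriptions could not be matched to any gene, the planned scan of annotation families could not be made, and no result of either is given. The part of the naming rule that excludes uncharacterized genes excluded none. In place of the lists, sets were made after the data were seen from the mitochondrial gene names and from the RNA classes of the table.

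Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter by group (17363 genes tested), 1 fit of all 12 libraries with 4 group means and 8 residual degrees of freedom, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common dispersion was 0.255, a biological coefficient of variation of 0.505. Levels are CPM with TMM-scaled library sizes, given as mean ± SD over 3 libraries. Adjusted p-values of single genes are from this edgeR fit unless another tool is named. The 6 comparisons were drought against control, T. hamatum against control, both treatments against control, against drought alone and against T. hamatum alone, and the interaction. The average effects of the fungus and of drought, each over 6 against 6 libraries, were added after the data were seen. Gene sets were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 11 sets with at least 3 tested genes.

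Named genes were taken from a rule fixed before the data were examined. In each comparison with at least 5 calls, it takes the 8 called genes with the highest and the 8 with the lowest log2 fold change, at a mean log2 CPM of at least 1 and with no overlap between the libraries of the 2 groups. With fewer than 5 calls it takes the 5 genes with the smallest p, given as values. The text describes some of these genes. A fold against a group whose libraries were all at 0 is a lower bound against a floor of 3 counts over the group, and such floors cover counting error only.

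Alternatives fixed before the data were examined were size factors in place of TMM, the DESeq2 1.42.0 Wald test, limma voom, no filter, a filter of at least 50 counts in 3 libraries, a log2 fold change of at least 1, the replicate number as a block, each library left out in turn and fits of only the 6 libraries compared. Added later were a fit without genes that were on and off among the libraries of 1 group, and the replicate number as a block for the libraries with the fungus only. The labels do not say what the replicate numbers mark. Residuals of same-numbered libraries of T. hamatum and of drought with T. hamatum correlated at 0.136, 0.237 and 0.101, each over 0.1, so the numbers were taken to pair the libraries of these 2 groups, a pairing that comes from the data alone. In no other pair of groups did all 3 pairs exceed 0.1.

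Library totals ranged from 15751682 to 24446349 counts. The tests were run on simulated counts drawn from the real means, library sizes and edgeR dispersions of 17363 genes with 200 changed genes. For drought against control, edgeR recovered 2.99% of 2-fold, 46.3% of 4-fold and 63.6% of 8-fold changes, and 3.85% of its calls were false. DESeq2 on the same simulated counts recovered 65.7% of 4-fold changes and 29.4% of its calls were false. For drought with T. hamatum against drought, edgeR recovered 47.8% of 4-fold changes, with 3.75% of its calls false. From the real edgeR p-values, an estimated 79.4% of genes were unchanged for drought against control. Genes that vary together can shift this estimate, so it does not count the genes that changed. Recovery and false shares depend on how many genes change, so the simulated ones need not hold for the real calls.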

Results

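Gene expression was measured in leaves of Cannabis sativa plants that were watered or left without water for 10 days, with or without T. hamatum in the soil. Each of the 4 groups had 3 libraries. Total counts per library ranged from 15751682 to 19898289 in control, from 18945798 to 24016016 in drought, from 15931574 to 24446349 in T. hamatum and from 21601095 to 24230678 in drought with T. hamatum. The labels do not state whether the libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, part of which may be technical. Counts of 2 libraries of a group differed by more than sampling noise in each group, with a chi-square per gene between 55.6 and 439. Between 19170 and 19952 genes had at least 1 count in a library.

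The first principal component, with 25.1% of the variance, placed all 12 libraries by the presence of the fungus. The 6 libraries with T. hamatum lay between 5.41 and 96.8 on it, and the 6 without lay between -103.4 and -35.2. Among those with the fungus, drought with T. hamatum lay between 5.41 and 42.83, and T. hamatum alone between 68.34 and 96.81. Control and drought libraries overlapped on this component. On the second component, with 15.7% of the variance, control lay between 47.93 and 76.49 and drought between -59.55 and 5.619. The groups with the fungus overlapped there, from -39 to 37.48 in T. hamatum and from -74.17 to 12.43 with both treatments. The median Pearson correlation of log2 CPM across genes was 0.905 within groups, 0.878 between groups with the same fungus state and 0.853 between fungus states. The lowest correlation within a group, 0.864, was between replicates 1 and 2 of drought with T. hamatum. These values describe the libraries and carry no test.

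**Figure D1:**
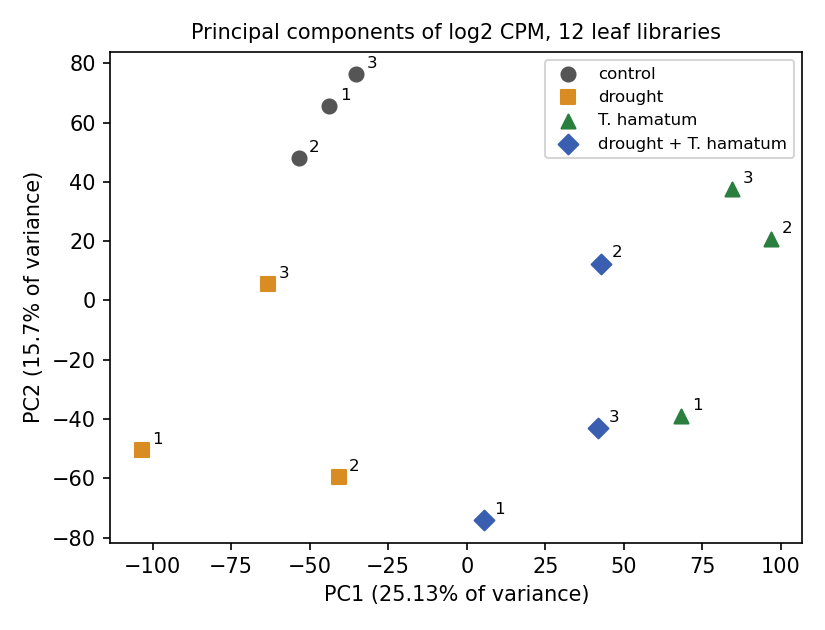
Principal components of log2 CPM of the tested genes, 1 point for each library, numbered by replicate, with colour and shape giving the group. The horizontal axis is the first component and the vertical axis the second, each in score units. The libraries with T. hamatum lie at 5.41 or higher on the first component, and those without it at -35.2 or lower.

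The comparison of T. hamatum with control asked what the fungus changed in leaves of watered plants. LOC115705224 rose from 54.4 ± 8.21 to 2590 ± 559 CPM (SD, n = 3; log2 fold change 5.57, SE 0.592, adjusted p = 0.00085). LOC133030624 rose from 0.359 ± 0.0822 to 104 ± 13 CPM (adjusted p = 0.000545), and LOC115704097 from 0.0332 ± 0.0574 to 11.3 ± 3.49 CPM (adjusted p = 0.00279). LOC115704852 fell from 63.3 ± 6.3 to 1.03 ± 0.517 CPM (log2 fold change -5.96, SE 0.437, adjusted p = 0.000178). LOC115700379 fell from 5.26 ± 1.46 to 0.0138 ± 0.024 CPM (adjusted p = 0.00169) and LOC115718830 from 4.09 ± 1.21 to 0.0411 ± 0.0366 CPM (adjusted p = 0.00274). The functions of these genes are not given in the sources used here. In all, 1149 genes passed the threshold, 609 higher and 540 lower, and 925 of them changed at least 2-fold. The count depended on single libraries. It was 604, 576 and 702 without control replicates 1, 2 and 3, and 643 and 707 without T. hamatum replicates 2 and 3, while the DESeq2 Wald test called 2555 genes.

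The same question was asked of plants without water by comparing drought with T. hamatum against drought alone. LOC115708243 stood at 9.01 ± 4.82 CPM in drought and rose to 702 ± 595 CPM with the fungus (log2 fold change 6.28, SE 0.843, adjusted p = 0.00296). It stood at 187 ± 51.9 CPM in control and 743 ± 356 CPM in T. hamatum alone. With only the 6 libraries of this comparison in the fit its adjusted p was 0.0537, the highest of 20 alternatives (lowest 1.11e-17). LOC115718505 had no count in the 3 drought libraries and 9.58 ± 2.05 CPM with both treatments, at least 221-fold higher (adjusted p = 0.0307). In watered plants it was not higher with the fungus. It stood at 18.7 ± 5.7 CPM in control and 6.19 ± 5.46 CPM in T. hamatum alone, where 1 library had no count. Its adjusted p was between 0.0534 and 0.0977 without any 1 of the control or drought libraries or without replicate 3 of both treatments, and between 1.71e-07 and 0.117 over all 20 alternatives. LOC115718500 fell from 35.1 ± 3.93 to 1.23 ± 0.446 CPM (log2 fold change -4.84, SE 0.431, adjusted p = 0.000568). LOC115715741 fell from 6.78 ± 3.06 to 0.196 ± 0.107 CPM (adjusted p = 0.00943, and 0.0523 without replicate 3 of both treatments, the highest of 20 alternatives, of which the lowest was 9.95e-13). In all, 978 genes passed, 476 higher and 502 lower. The count was 369 and 595 without drought replicates 1 and 3, 376 without replicate 3 of both treatments, 131 with only these 6 libraries in the fit and 2323 with DESeq2.

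**Figure D2:**
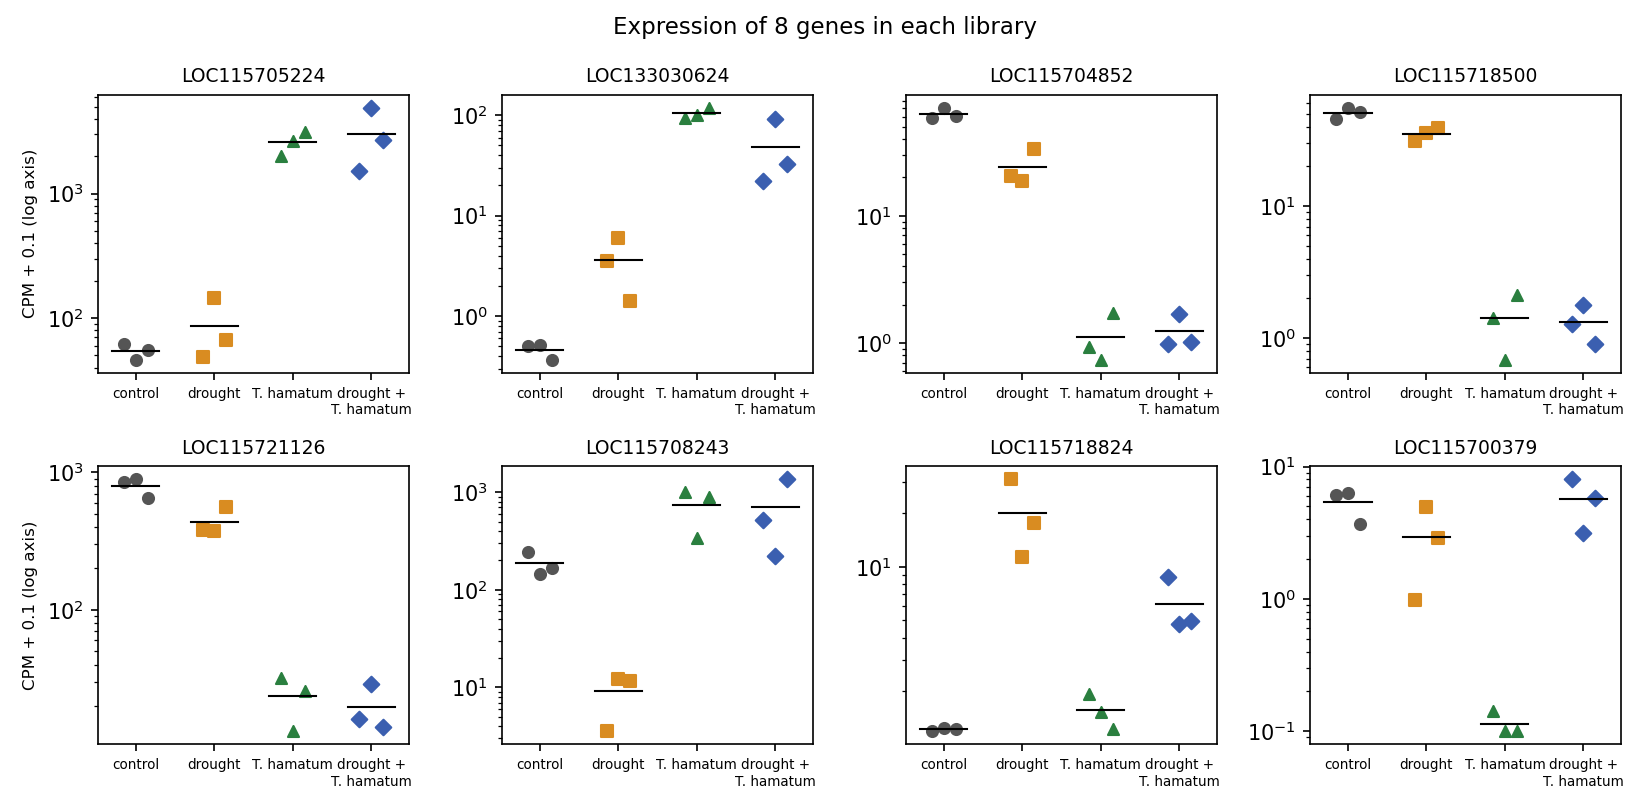
CPM of 8 named genes in each of the 12 libraries, on a log axis after adding 0.1. Points are libraries, horizontal bars are group means, and groups are given on the horizontal axis. LOC115705224 lies near 54.4 CPM in control and 2590 CPM in T. hamatum, and LOC115704852 lies near 63.3 CPM in control and 1.03 CPM in T. hamatum.

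The responses to T. hamatum in watered and in unwatered plants, measured on libraries that the 2 comparisons did not share, overlapped. Both were tested in 1 fit of all 12 libraries, with shared estimates of spread. There were 256 genes higher in both, against 16.7 for independent lists, and 260 lower in both, against 15.6. No gene was called in opposite directions (0 genes). Of the 1149 genes called in watered plants, 1089 had the same sign in unwatered plants (94.8%). Across all tested genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.415 and the Spearman correlation 0.451. The 516 genes called in both became 319, 301 and 320 without control replicates 1, 2 and 3, 284 and 322 without drought replicates 1 and 3, 342 without T. hamatum replicate 2, and 285 without replicate 3 of both treatments. Over both water states, 2701 genes passed, 1370 higher and 1331 lower.

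**Figure D3:**
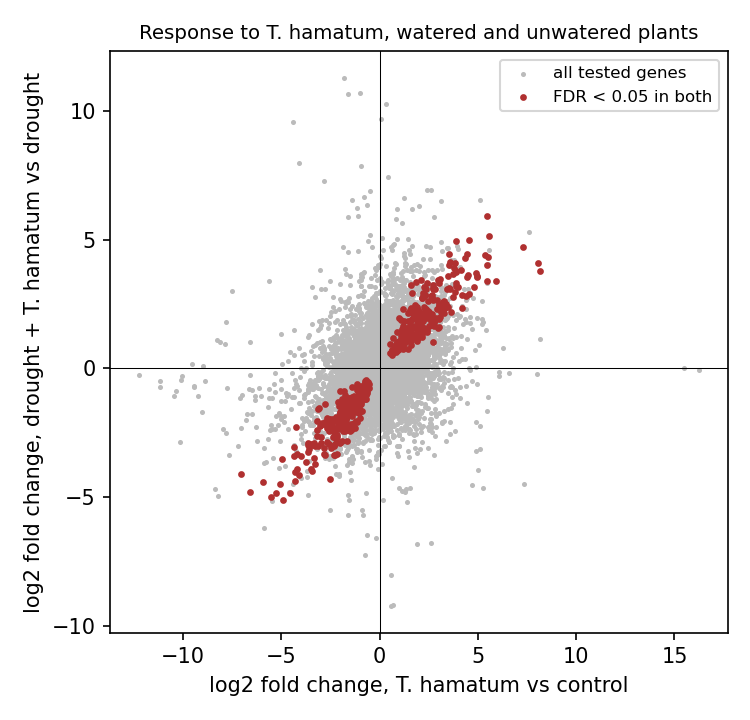
Log2 fold change of each tested gene with T. hamatum in watered plants (horizontal axis) against that in unwatered plants (vertical axis). Grey points are all 17363 tested genes and red points are the 516 genes called in both comparisons. The red points lie in the quadrants where both changes have the same sign.

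Plants with both treatments were compared with untreated control plants. LOC115705224 rose to 3035 ± 1720 CPM (log2 fold change 5.8, SE 0.599, adjusted p = 0.00055) and LOC133030624 to 48.7 ± 37.6 CPM (adjusted p = 0.000659). LOC115704097 rose to 4.37 ± 1.68 CPM (adjusted p = 0.00569). LOC115721126 fell from 801 ± 133 to 19.7 ± 8.16 CPM (log2 fold change -5.35, SE 0.441, adjusted p = 0.000177), LOC115718500 fell from 50.7 ± 4.99 to 1.23 ± 0.446 CPM (adjusted p = 0.000177), and LOC115704852 fell to 1.13 ± 0.392 CPM (adjusted p = 0.000158). LOC115711523 fell from 31.2 ± 9.31 to 0.52 ± 0.407 CPM (adjusted p = 0.0152, 0.053 without replicate 3 of both treatments and 0.0838 with limma voom, the highest of 20 alternatives, of which the lowest was 1.49e-07). In all, 610 genes were higher and 643 lower, 1253 together. The count was 608, 676 and 698 without control replicates 1, 2 and 3, 651 without replicate 3 of both treatments, 597 with only these 6 libraries in the fit and 2458 with DESeq2.

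Drought without the fungus was compared with control. LOC115718824 rose from 1.12 ± 0.0241 to 20 ± 10.2 CPM (log2 fold change 4.15, SE 0.449, adjusted p = 0.0482) and was the 1 gene that passed. Its adjusted p was 0.164 and 0.0568 without control replicates 1 and 2, 0.107 without drought replicate 1, 0.0662 and 0.0737 without T. hamatum replicates 1 and 2, 0.0543 and 0.119 without replicates 2 and 3 of both treatments, 0.0718 with only the 6 libraries compared in the fit and 0.113 with limma voom, with a lowest value of 1.98e-15 over 20 alternatives. The genes next in rank did not pass. LOC115694727 stood at 0.849 ± 0.434 CPM in control and 15.5 ± 3.2 CPM in drought, LOC115699629 at 17.6 ± 1.98 and 147 ± 49.7 CPM, and LOC115719679 at 28 ± 5.35 and 6.04 ± 1.87 CPM (adjusted p = 0.0923 for each). At an unadjusted p under 0.05 there were 2450 genes of 17363. DESeq2 called 758 genes and limma voom 0. Without single libraries edgeR called between 0 and 49 genes, the highest count being without control replicate 3.

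In plants with the fungus, drought with T. hamatum was compared with T. hamatum alone. No gene passed in edgeR (0 calls, smallest adjusted p = 0.18), with 2009 genes at an unadjusted p under 0.05, 480 calls by DESeq2 and 0 by limma voom. The smallest p belonged to LOC115700379, at 0.0138 ± 0.024 CPM in T. hamatum and 5.56 ± 2.45 CPM with both treatments. LOC115725461 stood at 0.954 ± 0.193 and 15 ± 4.51 CPM, and LOC115710338 at 6.17 ± 1.58 and 0.804 ± 0.214 CPM (adjusted p = 0.277 for both). Replicate 2 of drought with T. hamatum decided this count. Without it 415 genes passed, among them LOC115700379 (adjusted p = 0.00709), LOC115725461 (adjusted p = 0.014) and LOC115710338 (adjusted p = 0.0383). Over 21 alternatives the adjusted p of these 3 genes reached 0.594. With the replicate number as a block for the libraries with the fungus, a setting added after the data were seen, 1 gene passed. It was LOC115705140, chosen here after its values were seen, at 18.8 ± 12 CPM in T. hamatum and 119 ± 71.3 CPM with both treatments (adjusted p = 0.0106, and 0.277 without the block). With 1 and 0 calls the 2 drought comparisons could share no gene. Their log2 fold changes had a Pearson correlation of 0.191 and a Spearman correlation of 0.233 across genes. LOC115718824, the 1 gene called for drought against control, stood at 1.46 ± 0.353 CPM in T. hamatum and 6.06 ± 2.27 CPM with both treatments. It did not pass in this comparison.

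The interaction asked whether the effect of drought differed with the fungus. No gene passed in edgeR (0 calls, smallest adjusted p = 0.253), with 1449 genes at an unadjusted p under 0.05, 196 calls by DESeq2 and 0 by limma voom. LOC115698643 stood at 12.3 ± 3.38 CPM in control, 38.7 ± 4.23 in drought, 18.5 ± 6.96 in T. hamatum and 7.25 ± 1.23 with both treatments (adjusted p = 0.253). LOC115725461 stood at 1.46 ± 0.7, 0.486 ± 0.289, 0.954 ± 0.193 and 15 ± 4.51 CPM in the same groups (adjusted p = 0.253). Without replicate 2 of drought with T. hamatum 145 genes passed, these 2 among them (adjusted p = 0.028 and 0.024), and over 20 alternatives their adjusted p reached 0.5 and 0.411. With the replicate number as a block for the libraries with the fungus 1 gene passed, LOC115705140, at 113 ± 22.2 CPM in control and 35.4 ± 5.5 CPM in drought (adjusted p = 0.00313, and 0.322 without the block). The count was 9 without control replicate 3, 9 without T. hamatum replicate 3 and 1 without T. hamatum replicate 2.

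Mitochondrial transcripts were tested as a set formed after the data were seen. Whether counts from an mRNA kit follow the levels of these transcripts was not tested. The mitochondrial genome encodes subunits of the respiratory chain and ATP synthase. Against control, 28 of the 30 tested mitochondrial protein genes had a negative log2 fold change in drought (median -0.68) and 29 of 30 in T. hamatum (median -0.52), with 0 members passing singly in either comparison. With the preset correlation the set's adjusted p was 0.000159 in drought and 0.00168 in T. hamatum. With an estimated correlation, 0.455 between members, the adjusted p was 0.365 and 0.567. With fry it was 0.233 and 0.198. Without T. hamatum replicate 1 the preset adjusted p in T. hamatum was 0.132. With both treatments 25 of 30 members had a negative estimate against control (median -0.28), and the set did not pass (adjusted p = 0.57 preset and 0.917 with an estimated correlation). For example, cox1, a cytochrome oxidase subunit, stood at 5.01 ± 1.33 CPM in control, 3.21 ± 1.17 in drought, 2.2 ± 1.02 in T. hamatum and 2.84 ± 0.795 with both treatments. All mitochondrial genes together held 0.0453 ± 0.00847% of counts in control, 0.0337 ± 0.0196% in drought, 0.0247 ± 0.0142% in T. hamatum and 0.0304 ± 0.00339% with both (SD, n = 3). Most of this share was rRNA, so it does not give the level of the protein gene set. In control rrnL and rrnS stood at 187 ± 29.8 and 207 ± 45.1 CPM, and the highest protein gene, atp1, at 10.2 ± 1.28 CPM.

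**Figure D4:**
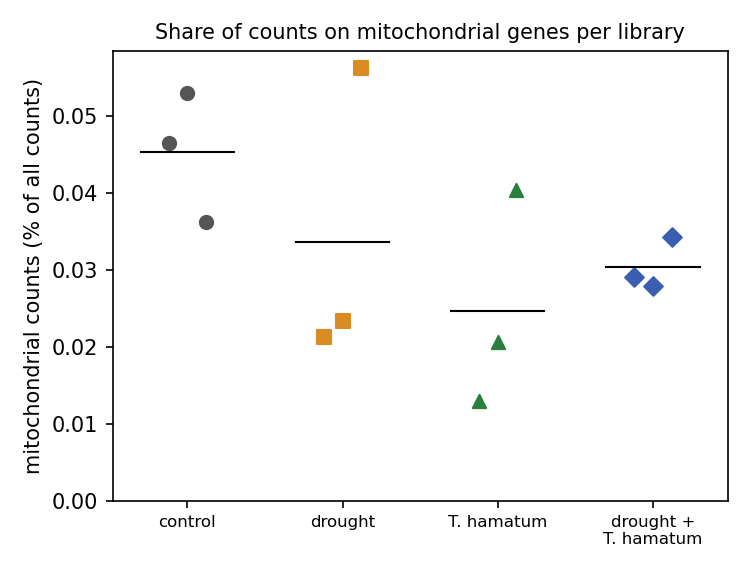
Share of all counts that fell on mitochondrial genes, in percent (vertical axis), for each library by group (horizontal axis). Points are libraries and bars are group means. Most of these counts are mitochondrial rRNA. The control libraries lie between 0.0363 and 0.0531%, and the T. hamatum libraries between 0.013 and 0.0405%.

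Small nucleolar RNAs guide chemical modification of ribosomal RNA. Of 1894 such genes in the count tables, 61 were tested. The libraries were made with an mRNA kit, so it is not known whether the counts measure the mature RNAs. Among the 61, 49 had a higher estimate with both treatments than with T. hamatum alone (median log2 fold change 0.60, preset adjusted p = 6.33e-05). With an estimated correlation the adjusted p was 0.606, and with fry 0.52. The preset adjusted p was 0.147 under the stricter filter and 0.0795 without replicate 3 of both treatments, and 0 members passed singly.

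Of the 6 nuclear genes with an older name in the reference, the cannabidiolic acid synthase gene LOC115697762 had at most 3 counts in a library, LOC115696884 (CBDAS2) had 0 (3 counts over the control group would be 0.0551 CPM), the terpene synthase gene LOC115716064 had at most 1, LOC115699293 (PKSG2) at most 2 and the olivetolic acid cyclase gene LOC115723438 at most 15. These 5 genes were below the filter and no difference was detectable at this depth. LOC115724170 (CHS), a chalcone synthase gene by its name, stood at 1.98 ± 1.22 CPM in control, 2.21 ± 2.92 in drought, 5.63 ± 3.76 in T. hamatum and 2.87 ± 1.06 with both treatments. It did not pass in T. hamatum against control (adjusted p = 0.417).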

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

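The gene sets below were chosen after the data were seen, and the difference was tested as the interaction of drought and T. hamatum. The log2 change with drought was higher in plants with the fungus than in plants without it for the mitochondrial protein genes (median difference 1.06), the mitochondrial rRNA genes (0.923), the small nucleolar RNA genes (0.558) and the long noncoding RNA genes (0.358), and lower for the small nuclear RNA genes (-0.729). Their preset adjusted p-values were 1.25e-08, 0.027, 0.0015, 0.027 and 0.027. None of these 5 sets passed with an estimated correlation, where the mitochondrial protein genes had an adjusted p = 0.222, the small nucleolar RNA genes 0.234 and the long noncoding RNA genes 0.241. None passed with fry, where the adjusted p lay between 0.168 and 0.236. No biological explanation was tested for these sets, nor whether counts from an mRNA kit measure their mature RNAs.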

How the results depend on the processing

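Direction was kept by all 63 genes of the naming rule, counted per comparison, in the 1255 values that the alternatives gave for them. The rule chose these genes on the same counts, for large changes without overlap or for the smallest p. A kept direction was therefore likely from the choice alone and says little about other genes. DESeq2 called more genes than edgeR throughout, with 758 for drought against control, 2555 for T. hamatum against control, 2458 for both treatments against control, 2323 against drought, 480 against T. hamatum, 196 for the interaction, 4060 for the average effect of the fungus and 1210 for that of drought. On simulated counts 29.4% of the DESeq2 calls for drought against control were false. Those counts used edgeR dispersions, 200 changed genes and only the filtered genes. The real DESeq2 run took all genes with a count, so this share need not hold for its calls. limma voom called 0 genes for drought against control and 0 for the average effect of drought. With only the 6 libraries compared the counts were 0 for drought against control, 1428 for T. hamatum against control, 597 for both treatments against control and 131 against drought. A log2 fold change of at least 1 left 1551 genes of the average effect of the fungus. Among 33 of these genes followed singly, limma voom ended 9 calls, the fit of 6 libraries 5 and the unfiltered fit 1. The block ended 5 and brought 2 over the threshold, and DESeq2 ended 0 and brought 9 over it. Leaving out single libraries ended their calls 51 times and brought genes over the threshold 12 times. The cause was not tested in any of these.

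With 1 library left out, counts ranged from 0 to 49 for drought against control, 576 to 1408 for T. hamatum against control, 608 to 1738 for both treatments against control, 369 to 1351 against drought, 0 to 415 against T. hamatum, 0 to 145 for the interaction, 1846 to 2975 for the average effect of the fungus, 0 to 650 for that of drought, and 284 to 629 for the overlap of the fungus responses. The highest counts against T. hamatum, for the interaction and for the average effect of drought came without replicate 2 of drought with T. hamatum, and the highest for drought against control came without control replicate 3.

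No label says that same-numbered libraries belong together. The pairing of T. hamatum with drought with T. hamatum is an assumption taken from weak residual correlations alone. Residual correlations of same-numbered libraries ran from -0.23 to 0.237, and 7 of 18 pairs exceeded 0.1. Of 12 libraries 5 correlated best with their own number, a count that was not compared with chance. With the number as a block, the replicate block gave 9 calls for drought against control and 10 for the average effect of drought, and stayed within 1.5 times for the other counts. The replicate block for the libraries with the fungus only, added after the data were seen, gave 1 call for drought with T. hamatum against T. hamatum, 1 for the interaction and 36 for the average effect of drought. It changed no call of the genes followed singly in the first 2 of these, of the mitochondrial protein genes in the interaction or of the small nucleolar RNA genes. Size factors in place of TMM moved the share of higher calls by less than 10 percentage points. The gene list tests and family scan were not run, since no gene descriptions were at hand.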

Other observations

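Tests of the overlap, of the correlation of the fungus responses over splits, of the fungus batch, of the drought libraries' spread and of neighbouring on and off genes were chosen only after the result was seen. The test of that spread and the splits of the interaction's calls are read as open against the bounds first written for them, a change made after their values were seen. The splits that keep pairs were added after the other results were seen, with their bounds set before they were run. The remaining tests were written down before their results.

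A set of 208 genes was on in at least 1 library of a group (over 20 CPM) and off in another of the same group (under 0.5 CPM). LOC133039947 had no count in the 3 control libraries and 242 ± 93.1 CPM in drought, while the T. hamatum libraries held 229, 0.266 and 1180 CPM. It passed in T. hamatum against control (at least 8550-fold higher, adjusted p = 0.0322, between 7.32e-14 and 0.626 over 18 alternatives). Without T. hamatum replicate 3 the bound was 2080-fold and the gene did not pass (adjusted p = 0.0638). It also did not pass without control replicate 1, 2 or 3 (0.084, 0.0892 and 0.0804), drought replicate 3 (0.0532), T. hamatum replicate 1 (0.0523) or replicate 3 of both treatments (0.0514). LOC115705719 held 6.32, 616 and 1230 CPM in control, 0.246 ± 0.0974 CPM in T. hamatum and 0, 1150 and 439 CPM with both treatments (adjusted p = 0.0482 for T. hamatum against control, between 6.35e-07 and 0.678 over 19 alternatives). Library depth is argued against, since 28% of the 318 off values lay in the shallowest library of their group. In 81 pairs of such genes within 5 tested genes of each other, the median correlation over libraries was 0.961, against at most 0.163 in 1000 permutations (permutation p = 0.001, the smallest they can give) and 0.0573 for other neighbours. This argues against reads moving from 1 neighbouring copy to another, though not against reads counted in both. Differences in genotype between the plants may therefore account for the pattern, as a hypothesis. Shared regulation of neighbours stays open, and no sequence was at hand to test either.

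The fungus response (2701 genes over both water states) exceeded each of 99 other splits drawn, the highest of which gave 543. The real split alone reached it (1 of 100). These splits ignore the assumed pairing of same-numbered libraries with the fungus, and none that keep it were run for the fungus. The correlation of the fungus responses, 0.415, was also reached by the real split alone (1 of 100), but by a small margin, as another split gave 0.407. The pairwise comparisons have 10 splits each, too few for a share under 0.05. The real and highest other counts were 1149 and 0 for T. hamatum against control, 1253 and 15 for both treatments against control, and 978 and 17 against drought. Of the genes called in both fungus comparisons, which share no library, 516 had the same direction and 0 opposite ones. Both lists came from 1 fit with shared estimates of spread, and genes that move together can agree by chance. The overlap was not counted over splits, so it adds no separate argument against chance differences between plants. The on and off genes themselves made up few of the calls. Without them 2725 genes passed, and 6 of the 2701 called genes were among them. Only 208 genes were removed, so removal alone could not bring a large fall. Genotype differences that coincide with the fungus groups were not removed, so this test leaves them open. A growth or library batch shared by the plants with the fungus cannot be told apart from the fungus, because 0 label values name a batch.

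For drought, edgeR called 1 gene alone and 1 as an average effect. As many calls came from 14 of 100 splits (here and below the real one included), with up to 137, so chance is not excluded for that count. Structure among the libraries may give the high splits, as a hypothesis that was not tested. For drought against control 2 of 10 splits gave as many, with up to 23, but 10 splits are too few for a share under 0.05. A count of 0 is reached by every split by construction, so 10 of 10 against T. hamatum (each with 0 calls) and 100 of 100 for the interaction (up to 39) decide nothing. The 3251 genes at an unadjusted p under 0.05 were reached by 3 of 100 splits, the highest of the others giving 4286, and the correlation of the drought responses, 0.191, by 9 of 100, up to 0.33. These splits ignore the assumed pairing of the libraries with the fungus. Among the 80 splits that part each of those pairs, as the real one does, and with the block for them, the real split was the highest (1 of 80) in calls (36, against at most 31), in genes at an unadjusted p under 0.05 (3809, against 3107) and in the correlation (0.186, against 0.173). That pairing was found on residuals from the real groups, which can favour the real split. A drought response spread over many genes may be present below the threshold, as a hypothesis. Whether the spread of the drought libraries prevents calls stays open. The same libraries gave 978 calls against both treatments, but larger changes can pass where smaller ones do not. On simulated counts 2.99% of 2-fold changes were recovered for drought against control, a share that depends on the 200 genes changed there. On and off genes are argued against as the reason for few calls, since 1 call was made without them. Without replicate 2 of drought with T. hamatum 650 genes passed for the average effect of drought.

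Genes called for the average effect of the fungus lay beside each other more often than in random placements. There were 51 rows of 3 or more neighbouring tested genes called in 1 direction, holding 167 genes, against a mean of 15.1 and at most 30 in 1000 random placements (permutation p = 0.001, the smallest they can give). The longest row had 7 genes, all lower, from LOC115698611 to LOC115701135. T. hamatum against control and both treatments against control had 8 rows each, against at most 6 (permutation p = 0.001 for each). Both treatments against drought had 3 rows, against at most 5 in the placements (permutation p = 0.041). Random placement takes no account of neighbours that vary together, and the cause of the rows was not tested.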
